A study of Homo sapiens with 8 samples.

How the data were processed

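Gene expression was measured on 8 Affymetrix 3' expression arrays, with 1 array for each of 2 treatments at each of 4 times. HepG2 is a human hepatocellular carcinoma line. The cells were kept in serum-free medium with or without 3 µM quercetin, a plant flavonol, and RNA from 4 times, 2, 4, 12 and 24 h, went to the arrays. The labels place the treatment after serum starvation but give its length differently for the series and for the samples, so that length is not used here.

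The authors deposited 1 table of log2 expression values for 54675 probe sets, made with RMA per the submitters' processing notes. The RMA version, its background and normalization settings and the probe description file are not given in the sources used here. The array medians lay between 7.36 and 7.48, but the SD of the values within an array ranged from 1.74 to 1.95, so the arrays did not share 1 distribution. Signal intensities before RMA were not used here, and the number of arrays limits the precision.

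Of the 54675 probe sets, 62 are Affymetrix controls, 41097 had exactly 1 gene symbol, 1801 had several and 11777 were not listed in the platform annotation used here. Symbols were updated through the Entrez identifier for 41043 of the 41097. Each of the 19775 symbols was represented by its probe set with the highest mean over the 8 arrays. The 13298 genes whose mean lay above the median of all probe sets, 7.43, were tested, and 6477 were left out as dim. Probe sets with several symbols were not named.

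Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, Benjamini-Hochberg adjustment, threshold 0.05). The model held time as a block and treatment as an added term, which leaves 3 residual degrees of freedom. The same model gave the contrasts of 4, 12 and 24 h against 2 h and the F-test over times. A second model asked whether the quercetin difference at 12 and 24 h differed from that at 2 and 4 h. Differences at a single time compare 1 array with 1 array and were described by size only, with a threshold of 1 on the log2 scale. A change was counted as shared by the times when the sign was the same at all 4 and the mean difference was at least 0.5 in size.

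Before the data were examined, 43 gene lists were fixed, of which 42 had at least 5 tested members. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The median of each list at each time was set against 10000 random lists of the same size, matched on mean expression in 20 bins. Random lists do not keep the correlation between members of a real list. A percentile is therefore not a p-value, and it can be extreme without an effect of treatment. Genes were named by a rule fixed at the same stage. It took the 10 largest mean differences in each direction among genes with the same sign at all 4 times, the 5 largest in each direction at each time, the 3 largest called effects in each direction for early against late, the 10 largest called rises and falls from 2 to 24 h with the same sign in both arms, and up to 4 members of each described list. Genes named beyond the rule are said to be so where they appear.

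The code was tested on simulated data with 200 of 13298 genes shifted. For quercetin against control over the 4 times, shifts of 0.5, 1 and 1.5 were recovered for 70.1%, 100% and 100% of genes, with 6.74% of calls false. For 24 h against 2 h the shares were 23.9%, 94.0% and 100%, with 5.84% false. For early against late they were 8.96%, 53.7% and 93.9%, with 3.70% false. Each simulated quercetin shift was the same at every time it covered, and the noise followed the variances moderated by eBayes. Real quercetin differences varied from time to time, so these shares do not give the recovery in the data. AKR1B10, with a mean difference of 0.95, was not called. In a simulation of 40 lists of 20 genes, 4 of 4 lists shifted by 0.3 were called and 0 of the others. Simulated genes were drawn independently, so this does not test lists with correlated members. In the data the estimated correlation was 0.416 for NRF2 antioxidant genes and 0.588 for glycolysis and hypoxia targets. It comes from residuals of the additive fit, which hold how the quercetin difference varies between times. A quercetin effect on a whole list that varies with time would thus add to it.

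The alternatives fixed beforehand were no filter or a filter at the 75th percentile, the mean of a gene's probe sets, gene-specific probe sets, every probe set on its own, median centring, cyclic loess, eBayes without trend or with robust moderation, array weights, no time or treatment block, other thresholds, another division of the times, an estimated correlation, and leaving out each time pair or each array. Quantile normalization and a block for array class were added after the data were seen. Array class divides the arrays at the widest gap in the mean signal of the hybridisation spike-in probe sets, which are transcripts added during the assay.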

Results

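The series asked how quercetin alters gene expression in HepG2 hepatocellular carcinoma cells held in serum-free medium. Control and quercetin-treated (3 µM) cells were profiled at 2, 4, 12 and 24 h, with 4 arrays per treatment and 1 array per treatment and time. No treatment and time had a replicate array, so p-values measure the spread of the quercetin difference across times and not the spread between cultures treated alike. An exact sign-flip test over the 4 times cannot give a two-sided p below 0.125.

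The mean signal of the 18S rRNA probe sets was 8.57 in the control and 12.01 in the quercetin array at 2 h, 11.52 and 11.62 at 4 h, 7.35 and 7.29 at 12 h, and 9.82 and 9.16 at 24 h. The hybridisation spike-in mean was low in the control array at 2 h (11.49) and in both arrays at 12 h (11.48 and 11.72), and lay between 12.07 and 12.34 in the other 5. The 2 h pair was thus the only pair that lay in different classes. The 3' minus 5' difference of ACTB ranged from 0.88 to 1.40 and that of GAPDH from 0.41 to 0.61. Within the 12 h pair ACTB was at 1.40 in control and 0.88 in quercetin, and GAPDH at 0.61 and 0.48. For ACTB both 24 h arrays (1.36 and 1.39) lay above both 2 h arrays (0.88 and 1.11). For GAPDH they lay below (0.41 and 0.42 against 0.47 and 0.56). The quercetin array at 2 h correlated across probe sets with its own control at 0.985, and the pairs at 4, 12 and 24 h at 0.992, 0.990 and 0.987. It correlated better with the control and quercetin arrays at 4 h (0.990 and 0.989) than with its own control, and the control array at 2 h correlated best with quercetin at 12 h (0.991).

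**Figure D1:**
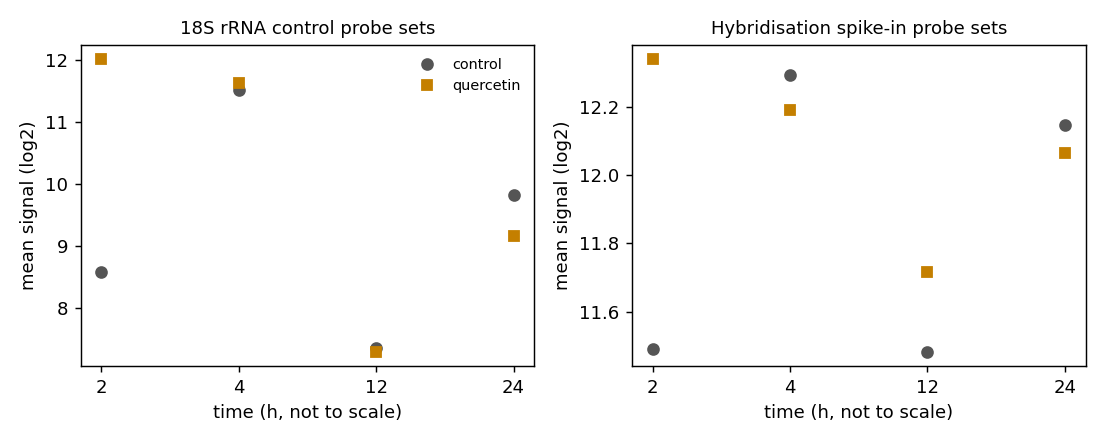
Mean log2 signal of the 18S rRNA probe sets (left) and of the hybridisation spike-in probe sets (right) against time in hours, 1 array per point, for control (grey circles) and quercetin (orange squares). The arrays of the 2 h pair differ by 3.44 in 18S signal, and those of the 4 h pair by 0.10.

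No gene was called for quercetin against control over the 4 times, and the largest mean differences with a shared sign are described here by size. AKR1B10, an aldo-keto reductase that detoxifies aldehydes, was 0.22, 1.34, 1.63 and 0.60 higher on the log2 scale at 2, 4, 12 and 24 h, a mean of 0.95 ± 0.16 (SE) or 1.93-fold. CYP1A1, the cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), was 1.37, 0.23, 1.86 and 0.29 higher, with a mean of 0.94 ± 0.19. SRXN1, which restores oxidised peroxiredoxins, was 0.55, 1.23, 0.65 and 0.20 higher (mean 0.66 ± 0.13), and TXNRD1, thioredoxin reductase, 0.52, 1.17, 0.47 and 0.08 higher (mean 0.56 ± 0.13). GCLM, a subunit of the enzyme that begins glutathione synthesis, was 1.33 higher at 4 h and 0.08 at 24 h, with a mean of 0.49 ± 0.16. ALPP (0.53), CATSPERG (0.48), PYCR3 (0.48), CFAP276 (0.47) and STAB2 (0.46) completed the 10 largest positive means. Of these, the sign for STAB2 turned with gene-specific probe sets (-0.042), and probe sets of CATSPERG and STAB2 disagreed in sign. With the mean of probe sets TXNRD1 was 0.30, CATSPERG 0.20 and STAB2 0.21. Without the 4 h pair GCLM was 0.20 and TXNRD1 0.36, and without the 24 h pair CATSPERG was 0.27 and PYCR3 0.30.

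The 10 largest negative means with a shared sign were those of HINT3 (-0.72), PLXNC1 (-0.63), MYO6 (-0.60), FAM13B (-0.60), SLCO4C1 (-0.57), IGIP (-0.55), DENND1B (-0.55), GRHL1 (-0.53), ZNF711 (-0.53) and CREBZF (-0.52). PLXNC1, a semaphorin receptor, was lower at each time (-0.54, -0.49, -0.81 and -0.69), while HINT3 differed by -1.64 at 12 h and -0.21 at 4 h. Probe sets of MYO6 and CREBZF disagreed in sign. With the mean of probe sets MYO6 was -0.03, CREBZF -0.14 and GRHL1 -0.26, and CREBZF was -0.28 without the 2 h pair and HINT3 -0.41 without the 12 h pair. Limma called 0 of 13298 genes at the adjusted threshold, and 785 genes (5.90%) had an unadjusted p under 0.05. The smallest adjusted p was 0.116, for AKR1B10. Without the 2 h pair AKR1B10 was called (mean 1.19, adjusted p = 0.00216), and over 16 alternatives its adjusted p ranged from 0.00216 to close to 1. AKR1B10 was also the 1 gene called with array weights and with the array class as a block. Only the 2 h pair differs in class, so the class block repeats the call without that pair. Gene-specific probe sets called 1 gene, AKR1C1 (named after its call was seen), every probe set on its own called 1 probe set, and the other alternatives called 0, with 71 genes at an unadjusted p under 0.05 without the time block and up to 1198 in the others. The sign was the same at all 4 times for 1838 genes (13.8%, where chance gives 12.5%), and 21 of these had a mean of at least 0.5 in size, 5 higher and 16 lower. That division was 5 and 24 after median centring, 7 and 12 after cyclic loess, and 7 and 9 after quantile normalization. It turned to 17 higher and 12 lower, of 29, without the 2 h pair, and to 5 and 4 with the mean of probe sets. The count was 126 without the 4 h pair, 85 without the 12 h pair and 42 without the 24 h pair, where fewer times had to share a sign.

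**Figure D2:**
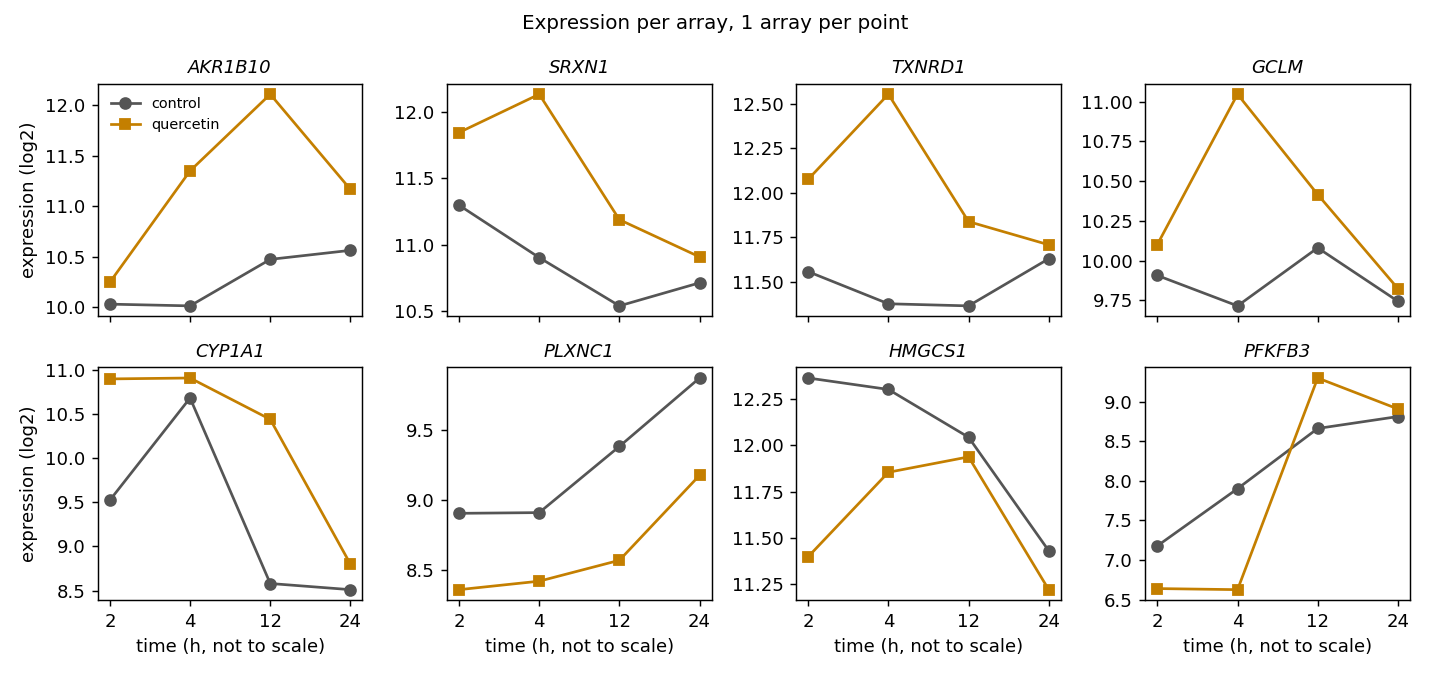
Log2 expression against time in hours (not to scale) of 8 genes in control (grey circles) and quercetin (orange squares) arrays, 1 array per point with lines joining the times of a treatment. AKR1B10, SRXN1, TXNRD1, GCLM and CYP1A1 lie higher with quercetin at all 4 times, PLXNC1 and HMGCS1 lower, and PFKFB3 is lower at 2 and 4 h and higher at 12 and 24 h.

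NRF2 antioxidant genes, targets of the main transcription factor of the oxidant response, were higher with quercetin as a group. Of 23 measured members, 18 were higher at 2 h, 23 at 4 h, 22 at 12 h and 13 at 24 h, and 12 were higher at all 4 times. The median difference was 0.09, 0.24, 0.36 and 0.03, at percentiles 100, 100, 100 and 99.64 of matched random lists. It was 0.22, 0.30, 0.25 and 0.08 after cyclic loess and 0.20, 0.30, 0.25 and 0.07 after quantile normalization, with 18 members higher at 12 h under both. Lists that were not called also reached extreme percentiles at single times. Respiratory chain genes lay at percentile 0 at 12 h, and gluconeogenesis and fasting genes at 99.83 at 4 h. No member was called over all genes tested, and 13 were called when adjusted over the list alone, all higher: AKR1B10, AKR1C1, AKR1C2, AKR1C3, GCLC, GCLM, GPX2, GSR, NQO1, OSGIN1, SRXN1, TALDO1 and TXNRD1. The AKR1C genes are close paralogs whose probe sets can share signal, so their separate values are uncertain. Camera gave an adjusted p of 4.66e-19 at the preset correlation, and the adjusted p was 0.985 with an estimated correlation. The list was called in 13 of 14 alternatives, with adjusted p values from 8.64e-29 to 0.985. The call was lost with the estimated correlation, which was 0.416 for this list. The other alternatives kept the preset correlation. This count, and the like counts given for other lists, thus do not test the choice of correlation.

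AhR targets had medians of 0.28, -0.01, 0.35 and -0.08 over 6 members, at percentiles 99.68, 60.43, 99.53 and 54.25 of matched random lists. Of the 6, 4, 3, 5 and 3 were higher at these times, and 2 at all 4. The medians were 0.28, 0.02, 0.24 and 0.02 after cyclic loess and 0.27, 0.01, 0.21 and -0.002 after quantile normalization. CYP1A1 and NQO1 (mean 0.26), a quinone reductase, were the 2 members called when adjusted over the list alone, and 0 were called over all genes. TIPARP, another target, had a mean of -0.21 and did not pass. The adjusted p was 0.0192, and 0.985 with an estimated correlation (range 0.000213 to 0.985, called in 7 of 12 alternatives). The call was lost without the 2 h pair (adjusted p = 0.0840), without the 12 h pair (0.140) and with the array class as a block (0.0845). Only the 2 h pair differs in class, so the class block takes up that pair's difference and repeats its omission.

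Cholesterol synthesis and uptake genes had negative medians with quercetin at the early times. Their median was -0.40 at 2 h, -0.29 at 4 h, 0.11 at 12 h and -0.13 at 24 h, with 16, 16, 5 and 14 of 18 members lower. It was -0.24, -0.26, 0.004 and -0.02 after cyclic loess and -0.26, -0.27, 0.005 and -0.04 after quantile normalization. HMGCS1, which makes the precursor of mevalonate, differed by -0.97, -0.45, -0.11 and -0.21, and STARD4, a sterol carrier, by -0.92, -0.42, -0.19 and -0.24. These 2 were called when adjusted over the list alone, and 0 over all genes. The adjusted p was 0.000295, and 0.985 with an estimated correlation (range 9.57e-10 to 0.985, called in 12 of 14 alternatives). It was 0.145 without the 4 h pair. The 18S signal of the 2 h arrays differed by 3.44.

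The list of metallothioneins, small metal-binding proteins, also holds the zinc transporter SLC39A10. It had medians of -0.27, -0.27, 0.05 and -0.27 over 8 members, and MT1F was lower at every time (mean -0.28). Over the times the median was -0.19, and -0.13 after cyclic loess and -0.12 after quantile normalization. By time it was -0.10, -0.23, -0.04 and -0.13 after cyclic loess and -0.09, -0.23, -0.05 and -0.11 after quantile normalization. The adjusted p of this list was 0.00677, and 0.985 with an estimated correlation (range 0.000839 to 0.985, called in 10 of 13 alternatives), and 0.145 without the 4 h pair. RNA splicing genes had medians of -0.26, -0.11, 0.06 and -0.07 over 39 members, with SRSF6 (-0.30), RBM5 (-0.30) and SRSF4 (-0.24) lower at every time. Over the times the median was -0.09, and -0.04 after cyclic loess. By time it was -0.11, -0.09, -0.07 and 0.04 after cyclic loess and -0.14, -0.09, -0.09 and 0.02 after quantile normalization, so the signs at 12 and 24 h turned. Their adjusted p was 0.0106, and 0.985 with an estimated correlation (range 0.000587 to 0.985, called in 8 of 14 alternatives), with 0.227 without the 2 h pair and 0.147 without the 4 h pair. The p53 targets had medians of -0.17, -0.03, 0.03 and -0.22 over 25 members, with PPM1D at -0.44 and RRM2B at -0.38 on average. Their adjusted p was 0.0295, and 0.985 with an estimated correlation (range 0.00449 to 0.985, called in 5 of 14 alternatives), with 0.291 without the 2 h pair and 0.150 without the 24 h pair. The call was also lost after cyclic loess, with medians of -0.03, 0.002, -0.06 and -0.11, and after quantile normalization, with -0.01, -0.01, -0.06 and -0.09. Ribosomal proteins had a median of 0.03 over 40 members, which was 0.01 after median centring and 0.02 after cyclic loess and turned to -0.00076 after quantile normalization, with the call lost under all 3. Their adjusted p was 0.00677, and 0.985 with an estimated correlation (range 2.03e-05 to 0.985, called in 6 of 14 alternatives), with 0.0611 without the 4 h pair and 0.148 without the 12 h pair. In these 4 lists 0 members were called over all genes or when adjusted over the list alone. In all, 7 of 42 lists were called at the preset correlation and 0 with an estimated one. With the estimated correlation 1 list, NRF2 antioxidant genes, had an unadjusted camera p under 0.05 (0.0478). For the other called lists that p ranged from 0.121 (AhR targets) to 0.391 (ribosomal proteins). The adjusted p of 0.985 was shared by these lists and does not rank them. Without the 4 h pair 3 lists were called. Without the 2 h pair 8 were, some of which the 4 times together did not call. By camera these were ribosome biogenesis (adjusted p = 0.00252), YAP and serum response targets (0.0188) and TGF-beta targets (0.0334), all higher. Replication-dependent histones (0.0334) were lower.

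The list of glycolysis and hypoxia targets was not called over the 4 times (adjusted p = 0.0551), and its median had opposite signs early and late. The median was -0.35 at 2 h and -0.24 at 4 h, both at percentile 0 of matched random lists, then 0.22 at 12 h and 0.03 at 24 h, at percentiles 99.9 and 99.95. It was -0.24, -0.20, 0.06 and 0.12 after cyclic loess and -0.28, -0.20, 0.07 and 0.13 after quantile normalization, with 28 and 29 members higher at 24 h. Of 32 members, 29, 28, 8 and 11 were lower at these times. PFKFB3, which makes the activator of glycolytic phosphofructokinase, differed by -0.54, -1.27, 0.64 and 0.10, and KDM3A, a histone demethylase induced by hypoxia that was named here after its values were seen, by -0.70, -0.86, -0.01 and 0.04.

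**Figure D3:**
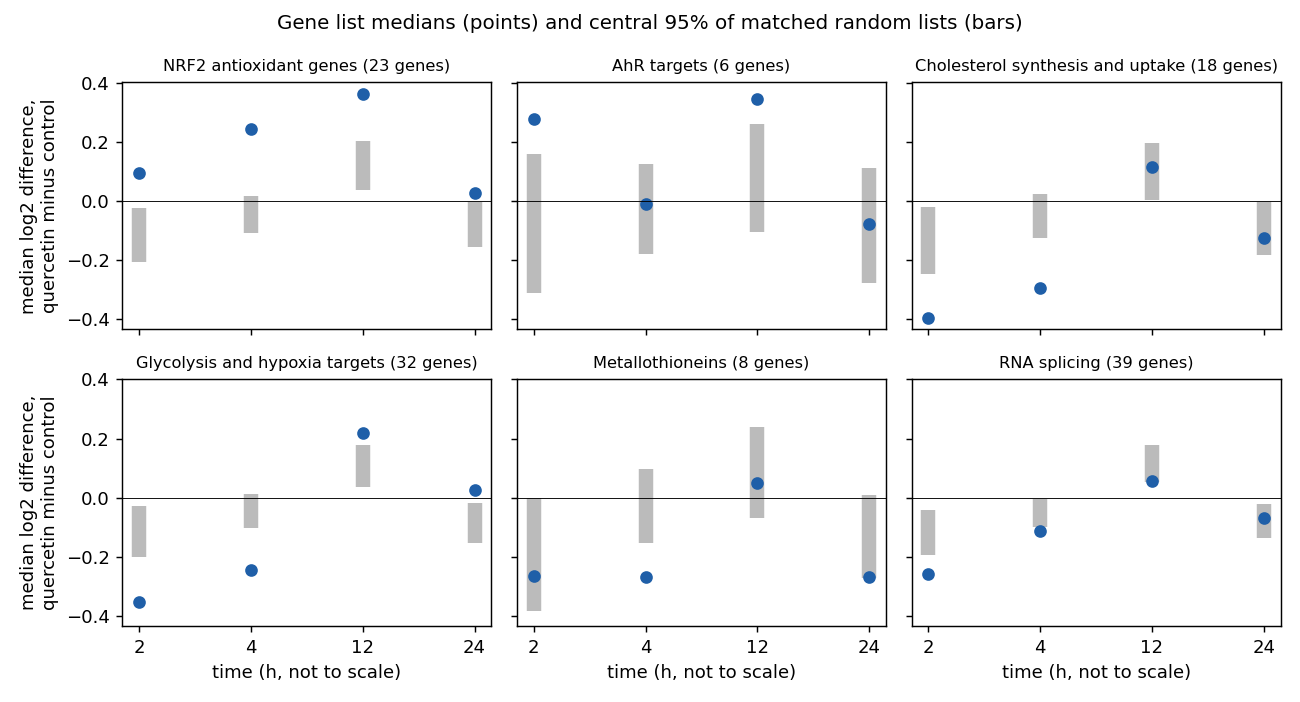
Median log2 difference, quercetin minus control, of 6 gene lists against time in hours (points), with the central 95% of 10000 matched random lists (grey bars). NRF2 antioxidant genes lie above the bar at all 4 times (0.09, 0.24, 0.36 and 0.03), and glycolysis and hypoxia targets lie below it at 2 and 4 h and above it at 12 and 24 h.

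Other lists that bear on quercetin did not pass. Over the 4 times the adjusted p was 0.956 for heat shock genes (19 members, median -0.03), 0.199 for mitotic genes (40 members, median -0.07) and 0.821 for G1/S and replication genes (36 members, median -0.05). Mitotic NUF2 (-0.33) and CENPE (-0.30) were lower at every time. Markers of other cell types gave adjusted p values of 0.0592 for leukocyte markers (median 0.10), 0.954 for fibroblast markers (-0.07) and 0.871 for markers of other epithelial lines (0.01). Of the endothelial markers 3 were measured, too few for the test, with a median of 0.23.

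Single times differed in their leading genes. At 2 h, 16 genes were at least 1 higher and 47 at least 1 lower. RPL27A (3.45), RPLP2 (3.42), ND6 (2.88), PEG3-AS1 (2.30) and INHBC (2.13) were highest, and ARID4B (-1.35), LOX (-1.30), PCK1 (-1.28), ZBTB1 (-1.26) and KPNA5 (-1.25) lowest. The arrays of this pair also differed by 3.44 in 18S and by 0.85 in spike-in signal. At 4 h, 6 genes were higher and 3 lower, led by UNKL (1.49), AKR1B10 (1.34), GCLM (1.33), SRXN1 (1.23) and TXNRD1 (1.17), and by PFKFB3 (-1.27), DIAPH3-AS1 (-1.13), FAM131C (-1.09), TMCC1 (-0.997) and EBF4 (-0.99). At 12 h, 43 were higher and 3 lower, with CYP1A1 (1.86), QSER1 (1.67), AKR1B10 (1.63), PEG3-AS1 (1.62) and UBXN4 (1.56) highest, and HINT3 (-1.64), CYP3A5 (-1.02), TCP11L2 (-1.01), ZFHX4-AS1 (-0.99) and GDPD1 (-0.99) lowest. Over the times the other probe set of QSER1 had a mean of -0.069, against 0.58 for the one used. Those of UBXN4 had 0.039 and -0.20, against 0.36. The 3' minus 5' difference of ACTB was 1.40 in the control and 0.88 in the quercetin array of this pair. At 24 h, 31 were higher and 20 lower, led by NFIA-AS2 (1.60), TEX48 (1.42), LOC101927513 (1.35), SAMD15 (1.34) and ADRA1D (1.31), and by H3-3A (-1.82), RPL27A (-1.70), RPLP2 (-1.56), KLF12 (-1.35) and FAM43A (-1.32), where 18S differed by -0.66. In the 24 h control array ADRA1D (6.92), NFIA-AS2 (7.22), LOC101927513 (7.34) and SAMD15 (7.45) were dim, near or below the filter cutoff of 7.43. TEX48 was at 8.01. The 24 h count of 51 was 12 with the stricter filter and 89 with no filter. These differences have no test, and the median of all genes was -0.06, -0.02, 0.05 and -0.10 at 2, 4, 12 and 24 h. The share higher at 2 h was 25.4%, and 13.8% after median centring, 39.1% after quantile normalization and 65.4% (17 against 9) with the mean of probe sets. At 24 h it was 60.8%, and 73.7% after cyclic loess, 41.7% with the mean of probe sets, 48.1% with gene-specific or every probe set and 41.9% at 1.5-fold. Across genes, differences at any pair of times correlated between -0.16 and 0.20, and genes are not independent replicates.

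The quercetin difference at 12 and 24 h departed from that at 2 and 4 h for 49 genes, 37 of them higher late. RUSC1-AS1 (1.52), PFKFB3 (1.27) and PPP1R12A (1.27), a myosin phosphatase subunit, had the largest positive late minus early values. RPL27A (-2.74), H3-3A (-2.46) and RPLP2 (-2.32) had the largest negative ones, and RPL27A was 3.45 higher at 2 h, in the pair whose 18S signal differed by 3.44. The count was 0 without the trend (477 genes at an unadjusted p under 0.05), 0 after cyclic loess, 0 after quantile normalization, 1 with the mean of probe sets, 15 with no filter and 135 with every probe set. The division turned to 7 higher late and 8 lower with no filter, 0 and 1 with the mean of probe sets, and 0 and 5 for 2 h against the later times. The fit leaves 2 residual degrees of freedom, and its prior degrees of freedom were infinite.

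Over time in serum-free medium, 5064 of 13298 genes changed by the F-test. The test sets changes against the disagreement of the arms. Both arrays of a time shared a class at 4, 12 and 24 h. Array differences that go with time thus cannot be told apart from time in medium. By 24 h CCNG2, an atypical cyclin of resting cells, had risen by 3.49 ± 0.20 (SE), or 11.2-fold. ANKRD37, a hypoxia target (3.12), DEPP1, a fasting-responsive gene (2.96), FAM13A (2.68), MAFF (2.54), DUSP6, a phosphatase of ERK (2.48), FILIP1L (2.43), RSRP1 (2.35), PCK1, the entry enzyme of gluconeogenesis (2.31), and LPAR6 (2.31) rose as well. SMG1P5 fell by 1.94, HINT3 by 1.83, MALAT1 by 1.66, CYP1A1 by 1.55, PTGER3 by 1.46, CEBPA by 1.45, LOC101927166 by 1.40, RBL1 by 1.32, BMS1P1 by 1.31 and POLR1B by 1.30. The calls of MALAT1 and POLR1B were lost with other probe set choices (adjusted p up to 0.590 and 0.243), and that of CYP1A1 with robust moderation (0.0672, the highest of its 19 alternatives, from 6.99e-06). With the mean of probe sets CCNG2 had risen by 1.18, with 0.38 for the 1 other of its probe sets above the filter, and FILIP1L by 1.61. HINT3 had then fallen by 0.72, LOC101927166 by 0.62 and BMS1P1 by 0.67, and the values of MALAT1 and POLR1B were -0.46 and -0.34. FAM13A was at 1.05 after quantile normalization, and with gene-specific probe sets MALAT1 was at -0.20. The other probe set of PTGER3 above the filter was at -0.23, and both were dim (means 7.62 and 7.63, cutoff 7.43). Probe sets of MALAT1, POLR1B, FOSL2, OIP5-AS1, CYP1A2, SRSF4 and TP53INP1 disagreed in sign at 24 h.

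From 2 to 24 h, 2831 genes changed, 2302 up and 529 down, and 2829 of them had the same sign in both arms. The fit calls a gene by how closely the arms agree, so these shared signs largely follow from the test. A change of at least 2-fold was seen for 435, of which 393 rose. The share that rose was 81.3%, and 87.6% after median centring, 60.2% after cyclic loess and 57.0% after quantile normalization, and the median of all genes was 0.09 as deposited, -0.02 after cyclic loess and -0.03 after quantile normalization. The count was 952 without the quercetin array at 2 h, 1057 without the control array at 24 h and 1574 without the quercetin array at 24 h. From 2 to 12 h 399 genes changed, 223 up, and 49 with the array class as a block. That count was 52 without the quercetin array at 2 h, 209 without the control array at 12 h and 607 without the quercetin array at 12 h, and the share that rose (55.9%) was 70% after median centring, 66.1% after cyclic loess and 68.4% after quantile normalization. It turned to 20.1% without the quercetin array at 12 h, 42.9% with the class block, 44.2% without the quercetin array at 2 h and 47.1% with the stricter filter. From 2 to 4 h 71 genes changed, 5 up, and 2 with the class block. That count was 2 without the control array at 2 h, 395 without the quercetin array at 2 h, 5 and 8 without the control and quercetin arrays at 4 h, 845 and 862 without those at 12 h, and 40 without either at 24 h. The share that rose (7.04%) was 44.4% after cyclic loess, 40.9% after quantile normalization and 50% without the control array at 2 h.

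Glycolysis and hypoxia targets rose by 24 h, with 19 of 32 members up and 0 down over all genes and over the list alone, and a median of 0.65 (adjusted p = 1.37e-08, and adjusted p = 0.808 with an estimated correlation, range 1.25e-11 to 0.808). The median was 0.29 in the control arm and 0.77 in the quercetin arm, each against its own 2 h array, and 0.42 over both after cyclic loess. ANKRD37 (3.12), PFKFB3 (1.95), KDM3A (1.92) and INSIG2 (1.80) led. Immediate early genes rose, with 15 of 25 up, 16 when adjusted over the list alone, and a median of 0.65 (adjusted p = 1.09e-06, and adjusted p = 0.808 with an estimated correlation, range 2.48e-08 to 0.808). The median was 0.35 after quantile normalization. DUSP6 (2.48), EGR1 (1.65), IER3 (1.65) and FOSL2 (1.52) were among them. Circadian clock genes rose, with 5 of 14 up, 7 when adjusted over the list alone, and a median of 0.47 (adjusted p = 0.0147, and adjusted p = 0.808 with an estimated correlation, range 0.00349 to 0.808). The median was 0.38 in the control arm and 0.57 in the quercetin arm. RORA (1.95), BHLHE40 (1.67), NFIL3 (1.36) and CRY1 (0.72) were among them.

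G1/S and replication genes fell by 24 h, with 12 of 36 down, 16 when adjusted over the list alone, and a median of -0.37 (adjusted p = 4.59e-10, and adjusted p = 0.808 with an estimated correlation, range 3.95e-16 to 0.808). The median was -0.49 in the control arm and -0.26 in the quercetin arm, and -0.56 over both after cyclic loess. CDC6 (-0.91), UHRF1 (-0.77), DTL (-0.66) and GINS3 (-0.59) were among them. The metallothionein list, which also holds the zinc transporter SLC39A10, fell, with 6 of 8 members down and 1 up over all genes and over the list alone, and a median of -0.80 (adjusted p = 5.62e-05, and adjusted p = 0.808 with an estimated correlation, range 5.81e-08 to 0.808). MT1X fell by 1.05, MT1G by 1.02 and MT2A by 0.93, while the zinc transporter SLC39A10 rose by 0.93.

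Mitotic genes rose, with 11 of 40 up, 16 when adjusted over the list alone, and a median of 0.29 (adjusted p = 0.0115, and adjusted p = 0.808 with an estimated correlation, range 0.000150 to 0.808). The median was 0.07 after cyclic loess and 0.05 after quantile normalization, with the call lost under both. CENPE (1.09), ASPM (1.05) and ECT2 (0.99) were among them. The p53 targets rose, with 8 of 25 up, 11 when adjusted over the list alone, and a median of 0.42 (adjusted p = 0.0473, and adjusted p = 0.808 with an estimated correlation, range 0.00334 to 0.808). The median was 0.20 after cyclic loess and 0.15 after quantile normalization, with the call lost under both and after median centring. PPM1D (1.36) and SESN1 (1.19) were among them. RNA splicing genes rose, with 13 of 39 up and 1 down, 15 and 2 when adjusted over the list alone, and a median of 0.23 (adjusted p = 0.0473, and adjusted p = 0.808 with an estimated correlation, range 0.00207 to 0.808). The median was 0.02 after cyclic loess and -0.0003 after quantile normalization, with the call lost under both. CLK1 (1.04) and PRPF3 (1.01) were among them. Each of these 3 lists was called in 3 of 10 alternatives. In the control and quercetin arms the medians were 0.22 and 0.36 for mitotic genes and 0.18 and 0.33 for RNA splicing genes.

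Cholesterol synthesis and uptake genes fell, with 4 of 18 down over all genes and over the list alone, and a median of -0.21 (adjusted p = 0.0371, and adjusted p = 0.808 with an estimated correlation, range 0.000440 to 0.808). The median was -0.20 in the control arm and -0.09 in the quercetin arm. It was -0.42 over both arms after cyclic loess and after quantile normalization. LSS (-0.59) and HMGCS1 (-0.56) were among them. Nuclear retained noncoding RNAs had a median of -0.26, or 0.0038 with the mean of probe sets, -0.45 after cyclic loess and -0.44 after quantile normalization (adjusted p = 0.0371, and adjusted p = 0.808 with an estimated correlation, range 0.00334 to 0.808). Of their 6 members MALAT1 (-1.66) fell and OIP5-AS1 (0.62) rose, and 1 rose and 2 fell when adjusted over the list alone. With the class block these 2 lists had adjusted p values of 0.467 and 0.0674. In all, 10 of 42 lists were called by camera at the preset correlation, 6 up, with 3 up of 10 after cyclic loess and 3 of 9 after quantile normalization. With an estimated correlation 0 were called, and 0 had an unadjusted p under 0.05. Among markers of other cell types, TEK (-0.71) and KLK3 (-0.71) fell. The other probe sets of KLK3 above the filter were at -0.12 and -0.35, and the median of other epithelial line markers was 0.12. AhR targets, NRF2 antioxidant genes and heat shock genes were not called at 24 h (adjusted p 0.118, 0.827 and 0.0755).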

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

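The tests of array class at 4 h, of scaling at 2, 12 and 24 h, the class block and quantile normalization were chosen only after the results were seen. The screen for single arrays far from the others was also widened after a first pass, from the array measures and first named genes to all named genes.

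Of 324 groups of 4 arrays examined, 13 had an array far from the other 3, where chance gives about 1 in 20. In the control arm these were KPNA5 at 4 h (8.62), RRM2B at 4 h (9.03), LTBP2 at 4 h (8.19), RPL27 at 12 h (14.38), and, at 24 h, LOC101927513 (7.34), DUSP6 (11.23), EGR1 (13.39), SRSF4 (12.26) and MT1X (10.04). In the quercetin arm they were ALPP at 12 h (7.46) and, at 24 h, DEPP1 (12.98), SNRNP200 (6.70) and GINS3 (8.88). The arrays of a group differ in time, so a late change alone sets an array apart.

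The late quercetin difference departed from the early one, by the interaction test, for 13 named genes. It was lower late for RPL27A (-2.74), H3-3A (-2.46), RPLP2 (-2.32), ND6 (-2.17) and INHBC (-1.16), and higher late for RUSC1-AS1 (1.52), PFKFB3 (1.27), PPP1R12A (1.27), LOX (1.17), UBXN4 (1.13), QSER1 (1.09), BHLHE40 (1.001) and TMCC1 (0.84). These are values of 1 probe set per gene. Probe sets of UBXN4, QSER1, PPP1R12A, LOX, BHLHE40 and TMCC1 disagreed in the sign of their mean quercetin difference. For PPP1R12A that mean was 0.036 in the probe set used and -0.28 and -0.12 in the others. No gene was called by this test without the trend, after cyclic loess or after quantile normalization. The named genes lower late, and LOX, each differed most at 2 h, in the pair whose arrays lie in different classes. Of the 3 ways to divide 4 times into pairs, the one used called 49 genes and the highest other 1. With 3 divisions, 1 of which gave as many, the splits are too few for a share under 0.05.

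Control probe sets outside the gene comparisons exceeded every control array in the quercetin arrays at 2 h for 18S (12.01), 28S (13.05) and the spike-ins (12.34), and at 4 h for 18S (11.62) and 28S (12.90).

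The large differences at 2 h lie in the pair whose arrays differ in class. Of the 63 genes that differed by at least 1, 81.0% differed in the same direction between classes measured on the arrays of the other times, just past the 80% that had been set as the bound. Without the 2 h arrays the lower class holds only the 12 h arrays, so this compares 12 h with 4 and 24 h and decides nothing about class. The share was 80.4% for the 12 h pair, whose arrays lie in 1 class. A quercetin effect lasting to 4 h could neither be shown nor excluded, since 57.1% of these genes had the same sign at 4 h. The 2 h array class and treatment cannot be told apart for single genes, as 1 array of each was measured.

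Glycolysis and hypoxia targets, lower early and higher late with quercetin, form the other pattern. Array class, 4 h part, is argued against, since both arrays share a class and the list lies at percentile 0. That percentile was known when the test was written, and a single pair of arrays cannot tell quercetin from other differences between them. Array class, 2 h part, stays open, since the median between classes (0.064) is likewise a contrast of times. Scaling is argued against at 4 h, where the percentile after quantile normalization is 0, and at 2 and 24 h, where after both scalings the percentiles nearest the middle are 0 and 99.96. At 12 h it stays open, since the median falls from 0.22 to 0.072 after quantile normalization and 0.059 after cyclic loess, at percentiles 99.57 and 97.34. A quercetin effect that differs between early and late times may remain, but the early against late test gave an adjusted p of 0.976 with an estimated correlation. That test was read first by its unadjusted p (0.0459), which would have favoured the explanation, and was changed to the adjusted p after the value was seen, since passing had been the stated need. The preset correlation gave an adjusted p of 1.30e-23.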

How the results depend on the processing

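Quantile normalization and the array class block were chosen after the data were seen, and the cause of each shift below was not tested, except that leaving out a time lowers the number of signs that must match. Time was the block in the fits, so each quercetin array was set against the control of its own time. Over the alternatives, 350 of 355 values of 24 h named genes kept direction and side of the threshold. For quercetin 310 of 314 did, each by staying uncalled. List calls held less: of 99 values at 24 h 33 lost the call and 2 reversed, and of 95 for quercetin 33 and 1.

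Genes called for quercetin were 1 with gene-specific probe sets, every probe set, array weights and the class block, and 0 to 1 without a time. Genes changed alike numbered 10 with the stricter filter, 9 with the mean of probe sets, 55 with every probe set, 312 at 0.3 and 0 at 1, and 29 to 126 without a time. Counts at 2, 4, 12 and 24 h were 26, 6, 15 and 24 with the mean of probe sets, 193, 23, 179 and 104 with every probe set, and 1050, 188, 417 and 673 at 1.5-fold. At 4 h they were 5 with the stricter filter and 16 after quantile normalization, and at 24 h 89 with no filter and 12 with the stricter filter. For time in serum-free medium, genes past the F-test were 2874 with the mean of probe sets.

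Genes changed from 2 to 4 h were 39 with no filter, 0 with the mean of probe sets, 6 with every probe set, 9 after cyclic loess, 22 after quantile normalization, 4 without trend, 141 with robust moderation, 2 with the class block, and 2 to 862 without an array. From 2 to 12 h they were 65 with the mean of probe sets, 257 with gene-specific probe sets, 161 without trend, 49 with the class block, and 52 to 607 without an array. From 2 to 24 h they were 1525 with the mean of probe sets and 952 to 3230 without an array.

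Lists called for quercetin were 2 with the mean of probe sets, 4 with gene-specific probe sets, 0 with an estimated correlation, and 3 to 8 without a time. At 24 h they were 16 with no filter, 4 with gene-specific probe sets and 0 with an estimated correlation. Early against late genes were 15 with no filter, 1 with the mean of probe sets, 32 with gene-specific probe sets, 135 with every probe set, 30 after median centring, 0 after cyclic loess, 0 after quantile normalization, 0 without trend and 5 for 2 h against later times.

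Directions reversed for STAB2 with gene-specific probe sets (-0.042), for nuclear retained noncoding RNAs at 24 h with the mean of probe sets (0.0038), for ribosomal proteins with quercetin after quantile normalization (-0.00076) and for RNA splicing at 24 h after quantile normalization (-0.0003).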

Other observations

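The tests of quercetin exposure, of array class at 4 h, of scaling at 2, 12 and 24 h and of the lists between early and late times, also after scaling, were chosen only after the results were seen.

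Between early and late times, lists other than hypoxia targets also differed in their quercetin effect. Cholesterol synthesis and uptake genes were higher late by a median of 0.41 (16 of 18 members, adjusted p = 6.77e-11), fatty acid synthesis genes by 0.22 (13 of 16, adjusted p = 0.000522), heat shock genes by 0.19 (16 of 19, adjusted p = 0.0155) and RNA splicing genes by 0.17 (32 of 39, adjusted p = 0.0168). Each adjusted p was 0.976 with an estimated correlation. After cyclic loess the medians were 0.29, 0.11, 0.12 and 0.08 (adjusted p = 2.04e-09, 0.00902, 0.140 and 0.381), and after quantile normalization 0.30, 0.10, 0.11 and 0.05 (adjusted p = 1.87e-09, 0.00891, 0.0487 and 0.464). The difference of RNA splicing genes was thus lost under both scalings and that of heat shock genes under cyclic loess. Scaling also brought calls that the deposited values lacked. NRF2 antioxidant genes were lower late by a median of 0.14 after cyclic loess (adjusted p = 7.99e-05) and 0.13 after quantile normalization (0.00570), against -0.02 as deposited (0.268). Respiratory chain genes were lower by 0.09 under both (0.00564 and 0.00570) but higher by 0.03 as deposited (18 of 32 members), so the direction turned. Ribosomal proteins (-0.15, adjusted p = 5.39e-15) and secreted liver proteins (-0.12, adjusted p = 0.0212) were called after cyclic loess alone. With an estimated correlation no list was called after either scaling, the lowest adjusted p being 0.341. Fatty acid synthesis genes had a median of -0.16 at 4 h, at percentile 0.29 of matched random lists, and -0.12 after either scaling. ATF4 and amino acid response genes, which include ASNS, had a median of -0.26 with quercetin at 24 h, at percentile 0 of matched random lists, with 26 of 30 members lower, and their adjusted p over the 4 times was 0.488. The median of all genes at 24 h was -0.10, and the list's median was -0.14 after cyclic loess and -0.13 after quantile normalization, at percentiles 0.03 and 0.09.

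The NRF2 antioxidant genes, higher with quercetin, were weighed as a pattern. Array class is argued against at 4 h only, where both arrays share a class and the list lies at percentile 100. That percentile was known when the test was written. A single pair of arrays cannot tell quercetin from other differences between them. Signal shared between aldo-keto reductases is argued against at 4 h, the only time at which the list was tested without them. There the 19 other members have a median of 0.31 and a percentile of 100. Scaling is argued against at 4 h (percentile 100 after quantile normalization) and at 2 and 12 h (percentile 100 after both scalings). At 24 h scaling may account for the list's place, since its percentile of 99.64 was 97.08 after quantile normalization and 96.08 after cyclic loess. Quercetin exposure as the cause stays open, since the list's place above the central 95% of random lists at 4 of 4 times is the pattern itself and tests nothing. Of 32 splits of the 8 arrays 4 gave a camera p as small as the real one (1.11e-20), but the other 3 carry the real contrast. In 2 of them (4.62e-47), which are 1 contrast under the time block, it is that of 4 and 12 h alone. In the other (9.99e-21) only 24 h is turned. The 8 splits that keep the time pairs are too few for a share under 0.05.

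Of the 35 splits of the arrays 32 could be fitted. As 0 genes were called for quercetin, all 32 gave as many whatever the data, so this count says nothing, and the highest other gave 10. For the lists called, 8 of 32 gave at least the real 7, the highest other giving 9, so chance is not excluded. Of these 8, 3 hold no net share of the real contrast. Splits with both arrays of a time on the same side come in pairs that are the same contrast under the time block. The splits counted are thus not all distinct, and such a pair is among these 3.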
